A study of Mus musculus with 10 samples.

How the data were processed

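The series holds RNA sequencing of mouse regulatory T cells (Treg, the CD4 T cells that depend on the transcription factor Foxp3 and restrain immune responses) from spleen and lymph nodes of C57BL/6 mice, in 10 libraries from 2 experiments. Per the labels' protocols, CD4 T cells were enriched on magnetic columns and sorted by flow cytometry, RNA was purified with the RNeasy Plus Mini kit, and libraries were made with the TruSeq Stranded mRNA kit. In the first experiment, Treg from mice with a Thy1.1 reporter of Foxp3 and a GFP reporter of Tcf7, the gene of the transcription factor TCF1, were sorted into 3 subsets by the lymph node homing receptor CD62L and by TCF1-GFP, with 2 libraries per subset. In the second experiment, Treg were sorted by YFP from heterozygous Foxp3-cre mice, with 2 libraries of wild-type Treg (WT) and 2 libraries of Treg with loxP-flanked Tcf7 and Lef1 (dKO). Lef1 encodes a transcription factor closely related to TCF1. The labels do not say whether the replicates came from separate animals, so the p-values measure the spread between these libraries, which may be technical.

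The deposited values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library). Per the submitters' processing notes, STAR and Cuffdiff were used with the GRCm38 build; their versions, the gene annotation and the scaling between libraries are not given in the sources used here. No counts or library totals were used here, so the absolute depth of each library is unknown. Relative depth was read from the lowest values: where a gene holds 1 fragment in each of 2 libraries, the ratio of its FPKM values is fixed, and genes under 0.3 FPKM piled up at such a ratio. By this measure WT replicate 2, dKO replicate 1 and dKO replicate 2 had 72.1%, 67.6% and 71.5% of the depth of WT replicate 1. Relative to CD62L+TCF1+ replicate 1, the depth was 93.4% for CD62L+TCF1+ replicate 2, 109% and 88.2% for the CD62L-TCF1+ libraries, and 88.2% and 81.6% for the CD62L-TCF1- libraries.

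The tables of the knockout experiment each hold 32767 genes, followed by 32767 blank rows. Their gene identifiers, in order, end before those of 22945 of the 55450 genes of the GENCODE vM21 annotation (GRCm38), of which 1757 are protein-coding; these genes were not analysed here. Of the identifiers, 32503 are in that annotation, from which coordinates were taken. A spreadsheet had turned 27 gene names into dates, and these names were restored by identifier. Several genes that every cell uses were listed at exactly 0, so a 0 is reported only as listed at 0, with the value of each library and no fold.

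The tables of the subset experiment hold 46073 features. The identifier column of these tables was in identifier order, while all of the consecutive rows with a value above 0 (100% of 21716 rows, at a tolerance of 1e-09 FPKM) stood in descending order of the mean CD62L-TCF1- value minus the mean CD62L-TCF1+ value. For the other pairs of subsets, 51.1% and 49.5% of consecutive rows were in descending order. Read by these identifiers, B2m, Gapdh and Foxp3 were at 0 FPKM in each of the 6 libraries and Pbsn, a prostate gene, reached 52134 FPKM. Across 6820 genes with at least 10 FPKM in the knockout experiment, the mean FPKM of the 2 experiments had a Spearman rho of 0.071, against 0.958 between WT and dKO. The identifiers therefore do not belong to the values beside them. The rows are in the same order in all 6 tables, so each row was used as a feature without a name, and no gene name is reported for the subsets. The planned gene lists in the subsets, the subset signatures in the knockout, the relation between the TCF1 gate and the knockout, and a joint fit of all 10 libraries need those names and were not run.

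Tests were made with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1) of the deposited values, over genes or features with at least 1 FPKM in at least 2 libraries of the fit, with moderated variances that follow a trend with expression, two-sided p-values and Benjamini-Hochberg adjustment at 0.05. A log2 fold change on this scale understates the change of weakly expressed genes. The knockout fit used its 4 libraries and 10710 genes, with 2 residual and 2.85 prior degrees of freedom. The 3 subset comparisons shared 1 fit of 6 libraries and 11879 features, with 3 residual and 2.06 prior degrees of freedom. Of 24 gene lists fixed before the data were examined, the 21 with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over those lists, and again with an estimated correlation. A list of plasmacytoid dendritic cell markers was added after the data were seen. The rule for named genes, fixed at the same time, took a few fixed genes, among them Tcf7, Lef1 and Foxp3, the 10 genes with the largest change in each direction among those past the threshold with a mean of at least 5 FPKM in a group and no overlap between the groups' libraries, and up to 4 passing members of each list. It left out unnamed gene models, receptor segments and small RNAs, and 1 further gene of the rule is not reported here. Rows were read and drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

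The fits were tested on simulated data with the real means, normal noise and variances drawn from the fitted prior, in which 200 genes with a mean above 5 FPKM were changed. Such noise follows the fit's own model, so the shares below show how the fit behaves where that model holds. They are not error rates of the real calls. In the simulated knockout comparison over 10594 genes, 12%, 78%, 100% and 100% of the genes changed by 0.5, 1, 2 and 3 on the log2 scale were recovered, and 3.33% of the calls were false. In the simulated comparison of CD62L-TCF1- with CD62L+TCF1+ over 11539 features, these shares were 10%, 68%, 96% and 92%, and 5.67% of the calls were false; in the other pairs of subsets, 66% and 70% of the features changed by 1 were recovered, with 6.25% and 6.43% of the calls false. A simulated list of 20 genes shifted by 0.5 in the knockout comparison gave a camera p of 6.4e-25, and 2% of 200 unchanged lists had a p under 0.05. The simulated genes were independent of each other, so this share does not apply to lists whose genes vary together. Examples are the cell cycle, Treg identity, ribosomal protein and follicular T cell lists, with estimated correlations of 0.88, 0.71, 0.50 and 0.42.

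The alternatives were other pseudocounts, filters, scalings and variance settings, the replicate number as a block, leaving out each library in turn, and other thresholds. Alternatives chosen after the data were seen were a fit without genes listed at 0 in any library, a fit of protein-coding genes, and list tests without Lef1 and Tcf7 as members.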

Results

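Gene expression was measured as FPKM in 2 experiments on sorted mouse Treg. The knockout experiment compared 2 libraries of WT Treg with 2 libraries of dKO Treg, in which Tcf7 and Lef1 carry loxP sites and Foxp3-cre marks the sorted cells. The subset experiment compared CD62L+TCF1+, CD62L-TCF1+ and CD62L-TCF1- Treg, with 2 libraries each. In the knockout experiment, between 10435 and 10678 genes per library reached 1 FPKM. In the subset experiment, between 10913 and 11290 features did so. Xist was present in the 4 knockout-experiment libraries at 39.5 to 55.3 FPKM, and none of 4 Y-linked genes exceeded 0.0294 FPKM.

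The first comparison asked how Treg differ when Tcf7 and Lef1 are deleted. Lef1 fell from 163 ± 4.35 FPKM in WT to 67.2 ± 6.20 FPKM in dKO (SD, n = 2 per group), a log2 fold change of -1.27 with a standard error (SE) of 0.09 and a limma adjusted p of 0.016. Tcf7 was at 479 ± 32.0 FPKM in WT and 294 ± 31.8 FPKM in dKO, with a log2 fold change of -0.70 (SE 0.10), and missed the threshold (adjusted p = 0.081), although both dKO libraries lay below both WT libraries. The labels do not say which exons are removed, and a gene-level FPKM includes the exons that stay, so these levels check the labels only in part. Foxp3, which defines the lineage, had 113 ± 9.92 FPKM in WT and 120 ± 8.40 FPKM in dKO (adjusted p = 0.69). On GRCm38, Lef1 lies on chromosome 3 from 131110471 to 131224356 and Tcf7 on chromosome 11 from 52252371 to 52283014.

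Among 10710 genes tested, 34 were higher and 41 were lower in dKO, and 1858 had an unadjusted p under 0.05. The passing genes comprised 54 named genes (25 higher and 29 lower), 13 small RNAs, 6 unnamed gene models and 2 receptor segments. Nedd4, a ubiquitin ligase, rose from 0.98 ± 0.20 to 32.4 ± 2.00 FPKM (log2 fold change 4.08, SE 0.12, adjusted p = 0.0011). Cyp4f18, a cytochrome P450 that acts on leukotriene B4, rose from 0.10 ± 0.025 to 18.8 ± 4.47 FPKM, which is 4.15 on the log2 scale with the pseudocount. Plac8, a small cysteine-rich protein, rose 6.30-fold to 19.9 ± 1.99 FPKM, and the interferon-induced membrane protein gene Ifitm3 rose 6.11-fold to 13.4 ± 2.02 FPKM. The cAMP phosphodiesterase gene Pde3b rose 5.50-fold to 32.5 ± 9.63 FPKM. Smaller rises were those of Cd7, a T cell surface protein (2.29-fold), Susd3 (2.23-fold), the peroxisomal enzyme gene Hsd17b4 (2.21-fold) and Id3, an inhibitor of E-protein transcription factors (1.69-fold).

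Myo6, a myosin motor, fell the most among the named genes, from 34.0 ± 6.35 to 2.38 ± 0.37 FPKM (log2 fold change -3.37, SE 0.16, adjusted p = 0.0059). The channel and receptor subunit genes Cnga1 and Gabrr2 were 6.68-fold and 5.79-fold lower, at 1.56 ± 0.081 and 1.71 ± 0.52 FPKM in dKO. The pyrin-domain gene Pydc3 was 3.43-fold lower and the ribosomal protein gene Rpl34 3.29-fold lower. Both belong to families with near-identical copies, so reads may be shared and these values are uncertain. Pydc4, a neighbour of Pydc3 outside the naming rule and chosen after its values were seen, passed in the other direction. Its log2 fold change was 0.90 (SE 0.07, adjusted p = 0.020). Whether reads were assigned differently between Pydc3 and Pydc4 was not tested. Ccdc109b, a subunit of the mitochondrial calcium uniporter, was 3.26-fold lower, the cytokine gene Tnfsf14 3.17-fold lower and Igfbp4 2.88-fold lower. Actn1, which cross-links actin, was 2.82-fold lower, and P2rx7, an ATP-gated channel, fell from 96.0 ± 7.10 to 36.2 ± 5.05 FPKM. For each named gene, both dKO libraries lay on the same side of both WT libraries, except for Foxp3. The naming rule required this of the genes with the largest changes, so for them it is no separate result.

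**Figure D1:**
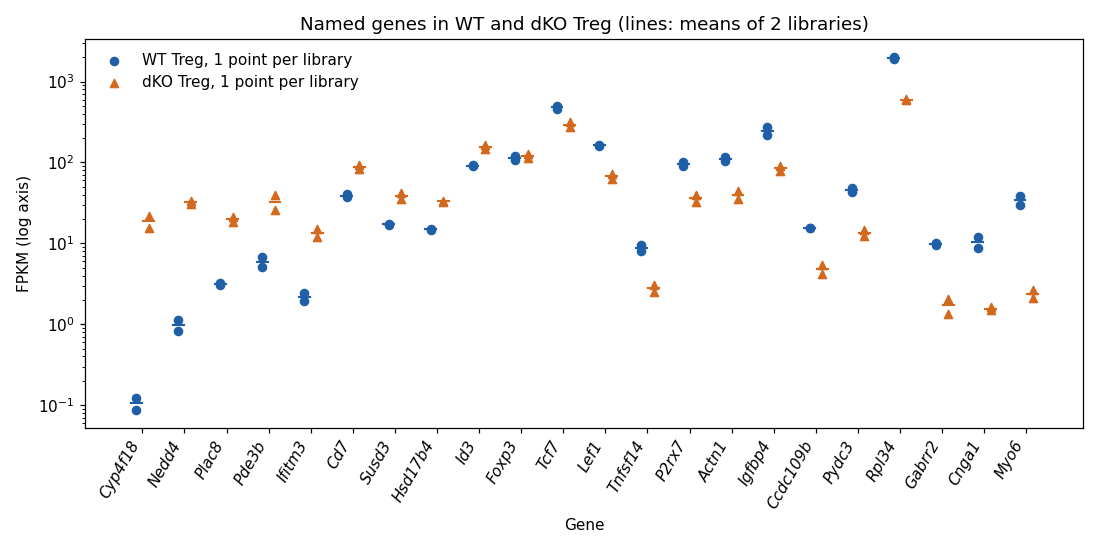
FPKM of the named genes on a log axis, with 1 point per library (circles WT, triangles dKO, n = 2 each) and short lines at the group means. Cyp4f18, Nedd4 and Plac8 stand above WT in both dKO libraries, Myo6, Cnga1 and Gabrr2 stand below, and the points of Foxp3 overlap; the 2 named genes listed at 0 in WT are not drawn.

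These counts rest on 2 libraries per group. Without WT replicate 1 there were 21 passing genes (19 higher and 2 lower), without WT replicate 2 there were 14 (11 and 3), without dKO replicate 1 there were 42 (9 and 33) and without dKO replicate 2 there were 136 (36 and 100), so the split of 34 higher and 41 lower depends on single libraries. Lef1 then missed the threshold without WT replicate 1 or 2 (adjusted p = 0.12 and 0.17), while its log2 fold change stayed at -1.30 and -1.25. Of the 18 passing genes listed at 0 in both libraries of a group, 9 were higher and 9 lower in dKO; without genes listed at 0 in any library, 117 genes passed (45 higher and 72 lower), and 171 (73 and 98) passed among protein-coding genes alone.

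Genes of follicular T cells, which help or restrain B cells in germinal centres, were lower in dKO as a set. Of 20 tested members, 19 had a negative log2 fold change, with a median of -0.49 (camera adjusted p = 1.3e-07). With an estimated correlation the adjusted p = 0.65. Without WT replicate 1 the median was -0.32. P2rx7 passed over all genes, and 7 members passed, all lower, when adjusted over the list alone. Cxcr5, the receptor that guides cells into follicles, went from 24.1 and 20.1 FPKM in the WT libraries to 7.21 and 10.8 FPKM in the dKO libraries, and Tnfsf8 from 29.5 and 30.5 to 14.3 and 17.7 FPKM. Slamf6 had a log2 fold change of -0.61 (SE 0.09), and Bcl6, the lineage's transcription factor, of -0.38 (SE 0.11). Cxcr4 was uneven, with 184 and 179 FPKM in WT but 17.9 and 93.7 FPKM in dKO.

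Treg identity genes were also lower as a set (14 of 18 tested members negative, median -0.46, camera adjusted p = 3.7e-04, and adjusted p = 0.65 with an estimated correlation). Without dKO replicate 1 the median was -0.24, and without dKO replicate 2 it was -0.61. No member passed over all genes, and 2 did when adjusted over the list alone. These were Gpr83 (63.3 and 70.4 FPKM in WT, 10.8 and 20.5 FPKM in dKO) and Izumo1r, the folate receptor 4 gene (483 and 440 against 216 and 300 FPKM). Ikzf2, which encodes Helios, had a log2 fold change of -0.90 (SE 0.27), while Il2ra had 0.33 (SE 0.10). Cytoplasmic ribosomal protein genes had negative log2 fold changes in 71 of 73 tested members, with a median of -0.16 (camera adjusted p = 3.2e-14, and adjusted p = 0.65 with an estimated correlation). Rpl34 alone passed, over all genes and adjusted over the list alone.

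Wnt target genes had 8 of 11 tested members negative and a median of -0.31 (camera adjusted p = 0.0025, and adjusted p = 0.65 with an estimated correlation), but this list holds the deleted Lef1 and Tcf7. Without these 2 genes, a test chosen after the data were seen, 6 of 9 members were negative, with a median of -0.27, and the list missed the threshold (camera adjusted p = 0.067). Adjusted over the list alone, 5 members were lower (Lef1, Tcf7, Jun, Rnf43 and Axin2) and Sox4 was higher (log2 fold change 0.86, SE 0.15). Without the deleted genes in the list, Jun (-0.85, SE 0.11), a subunit of the AP-1 transcription factor, and Rnf43, a ubiquitin ligase that restrains Wnt receptors, were still lower, while Axin2, a feedback inhibitor of the Wnt pathway (-0.33, SE 0.10), no longer passed. Without the expression filter the full list's adjusted p was 0.12. Naive and central memory genes went both ways (median -0.02, camera adjusted p = 0.40). Over all genes Id3 was higher and Lef1, Igfbp4 and Actn1 were lower, and adjusted over the list alone 5 were higher and 8 lower. Those 8 include the deleted Lef1 and Tcf7. Without these 2 genes, a test chosen after the data were seen, 5 were higher and 6 lower, with a median of 0.049 (camera adjusted p = 0.97). The higher ones included Klf2, with 281 and 277 FPKM in WT and 445 and 400 FPKM in dKO, and the lower ones included the homing receptor gene Ccr7, with 208 and 227 against 147 and 151 FPKM.

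Interferon-stimulated genes were higher in dKO as a set, with 27 of 30 tested members positive and a median log2 fold change of 0.20 (camera adjusted p = 1.4e-06, and adjusted p = 0.65 with an estimated correlation). No member passed over all genes, and 9 members, all higher, passed when adjusted over the list alone. Irf7 had 37.4 and 38.0 FPKM in WT and 60.6 and 51.4 FPKM in dKO, and Oasl1 had 4.33 and 4.71 against 7.13 and 7.91 FPKM. Gbp2 had a log2 fold change of 0.43 (SE 0.07). Oas1a went the other way, with a log2 fold change of -0.81 (SE 0.29).

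Cytokine and cytotoxic effector genes were higher as a set (14 of 19 positive, median 0.47, camera adjusted p = 0.010, and adjusted p = 0.65 with an estimated correlation). Adjusted over the list alone, 5 were higher and Tnfsf8 was lower, and none passed over all genes. Prf1, which encodes perforin, had 3.68 and 4.39 FPKM in WT and 17.5 and 10.9 FPKM in dKO, and Ccl5 had 35.1 and 16.9 against 65.4 and 84.1 FPKM. Markers of CD8 T and NK cells, which share Prf1, Ccl5 and Gzma with that list, had a median of 0.67 over 7 tested members (camera adjusted p = 0.049, and adjusted p = 0.65 with an estimated correlation), with Prf1 and Ccl5 higher when adjusted over the list alone. The other markers were uneven: Cd8a stayed at or under 0.488 FPKM, Cd8b1 had 14.1 to 16.5 FPKM in the 4 libraries, and Nkg7, a granule protein gene, had 30.3 and 15.9 against 22.5 and 31.8 FPKM. Without dKO replicate 2 the cytokine list had a median of 0.29 (adjusted p = 0.13) and the CD8 T and NK list one of 0.59 (adjusted p = 0.12), and without WT replicate 2 the cytokine list had a median of 0.34 (adjusted p = 0.095). Without dKO replicate 1 the cytokine median was 0.31. A mean of at least 5 FPKM ended the call of the cytokine list (adjusted p = 0.079), and median scaling (0.052) and no filter (0.16) ended that of the CD8 T and NK list.

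Cell cycle genes had positive log2 fold changes in 40 of 41 tested members (median 0.35, camera adjusted p = 5.4e-05, and adjusted p = 0.65 with an estimated correlation), and no member passed, over all genes or adjusted over the list alone. The libraries of a group differed widely: Top2a had 15.2 and 7.43 FPKM in WT and 12.3 and 19.6 FPKM in dKO, and Mki67 4.78 and 2.13 against 3.57 and 4.98 FPKM. Without WT replicate 2 the list had a median of 0.12 and an adjusted p of 0.41, and without dKO replicate 2 a median of 0.14 and an adjusted p of 0.12. Without WT replicate 1 or dKO replicate 1 the median was 0.59 and 0.55.

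Among the other sets, 4 passed camera at the preset correlation, all with an adjusted p = 0.65 with an estimated correlation. T helper lineage genes had a median of -0.18 (camera adjusted p = 0.049), with Stat4, Il18r1, Il12rb1 and Rora lower when adjusted over the list alone. Inhibitory and costimulatory receptors had a median of -0.25 (camera adjusted p = 0.025), with Cd160 lower when adjusted over the list alone, from 6.83 and 7.10 FPKM in WT to 1.98 and 3.18 FPKM in dKO. Glycolysis genes had a median of -0.15 (adjusted p = 0.027) and cholesterol synthesis genes a median of 0.15 (adjusted p = 0.032), with no member passing when adjusted over the list alone. Without WT replicate 1 these sets had medians of -0.01, -0.23, -0.15 and 0.014 (adjusted p = 0.73, 0.13, 0.081 and 0.88), and without dKO replicate 1 medians of -0.14, -0.07, -0.13 and 0.13 (adjusted p = 0.094, 0.38, 0.094 and 0.24). Without WT replicate 2 the T helper and cholesterol medians were -0.42 and 0.28, and without dKO replicate 2 the T helper and receptor medians were -0.35 and -0.46. T helper genes also missed the threshold with no filter (0.19), median scaling (0.065) and quantile normalization (0.061), and the receptors with no filter (0.086) and a mean of at least 5 FPKM (0.066).

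Sets that did not pass camera included effector Treg genes (median -0.17, adjusted p = 0.26), for which 3 members were higher (Ccr2, Gzmb and Fgl2) and 2 lower (Nt5e and Rora) when adjusted over the list alone. Without WT replicate 2 this list passed (median -0.37, adjusted p = 1.2e-04), and likewise without dKO replicate 2 (-0.32, 0.0053), while without WT replicate 1 its median was 0.12. Activation and immediate early genes had a median of -0.02 (adjusted p = 0.14), with Jun lower when adjusted over the list alone, and passed without WT replicate 2 or without dKO replicate 2 (adjusted p = 0.026 each). Homing receptors had a median of 0.04 but a mean of -0.13 (adjusted p = 0.40), with 1 member higher and 5 lower when adjusted over the list alone, among them Itga4 and Gpr15. Apoptosis genes had a median of -0.04 and a mean of 0.018 (adjusted p = 0.79), with no member passing. Conventional CD4 T cell genes had a median of 0.24 (adjusted p = 0.49), with Pde3b higher and Igfbp4 lower over all genes and 3 members higher and 3 lower when adjusted over the list alone. Mitochondrially encoded genes had a median of 0.015 (adjusted p = 0.16) and a mean of 1.59, which mt-Co1 sets because it is listed at 0 in WT; without WT replicate 2 this list passed (adjusted p = 0.0021).

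Markers listed for other cells ranged from absent to high. Ighm of the B cell list had 306 and 274 FPKM in WT and 263 and 238 FPKM in dKO, and Ctss and Cst3 of the myeloid list had 275 and 280 against 235 and 261 FPKM and 93.8 and 87.3 against 105 and 94.5 FPKM. Of the 18 myeloid markers, 5 were tested (median 0.87, camera adjusted p = 0.35), and several stood out in dKO replicate 2. There Lyz2 had 31.9 FPKM against 0.86 FPKM in dKO replicate 1, Tyrobp had 12.6 against 1.77 FPKM and Csf1r had 8.51 against 0.21 FPKM, while the WT libraries held 3.56 and 0.90 FPKM of Lyz2. Without dKO replicate 1 the myeloid list passed (median 1.56, adjusted p = 0.0061), and it also passed without the expression filter (0.040). B cell markers had a median of 0.64 over 7 tested members (adjusted p = 0.35), with Cd79b higher when adjusted over the list alone, and passed without WT replicate 1 (adjusted p = 0.0058). Of the erythroid markers only Car2 was tested (log2 fold change 0.11, SE 0.21), and of the plasma cell and stroma markers Xbp1 (43.8 to 56.1 FPKM), Pecam1 (57.9 to 71.2 FPKM) and Epcam (2.98 to 5.67 FPKM), none of which passed. The added plasmacytoid dendritic cell list had a median of 0.30 over 8 tested members (camera adjusted p = 0.017 as the only list in its adjustment, chosen after the data were seen, and adjusted p = 0.13 with an estimated correlation), with 2 members higher when adjusted over the list alone.

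**Figure D2:**
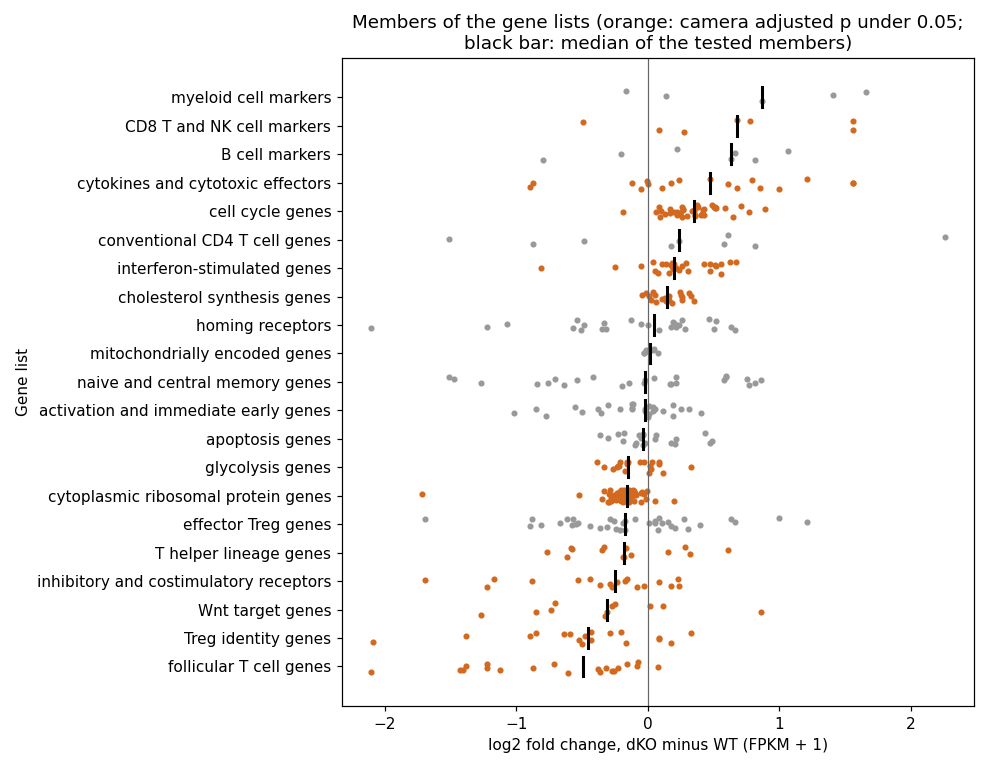
Log2 fold changes between dKO and WT Treg (2 libraries each) of the tested members of the 21 lists, 1 point per gene, with a black bar at the median of the tested members and orange points where the list had a camera adjusted p under 0.05. Follicular T cell and Treg identity genes lie lowest, with medians of -0.49 and -0.46, and members listed at 0 in any library are not drawn.

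Around Lef1 on chromosome 3, 3 other genes passed, all lower in dKO. Rpl34 (130726831 to 130730398) lies 0.38 Mb from Lef1, Ccdc109b (129914960 to 129970206) lies 1.14 Mb away and Camk2d, named after its values were seen, lies 4.26 Mb away with a log2 fold change of -0.78 (SE 0.08, adjusted p = 0.045). Within 10 Mb of Lef1 or Tcf7, 4 of 213 tested genes passed, the 2 targeted genes left out, against 70 of 10474 elsewhere (one-sided Fisher's exact p = 0.060). This test pools both windows, and the Lef1 window was not tested alone.

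**Figure D3:**
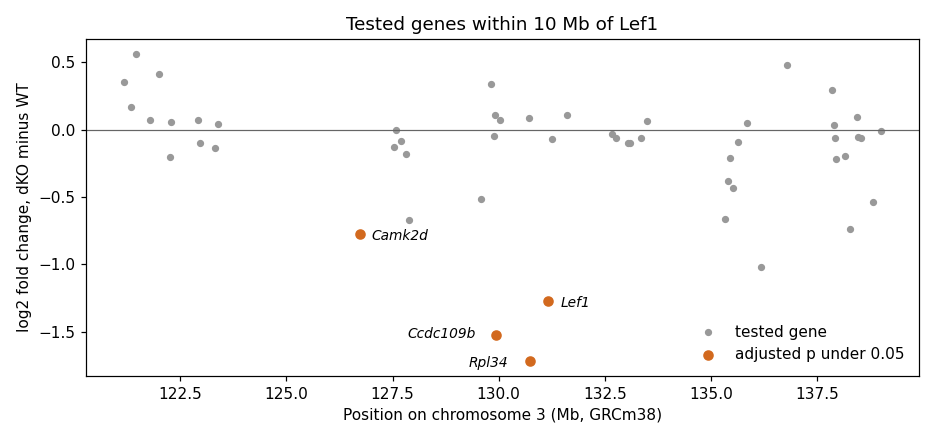
Log2 fold change between dKO and WT Treg of the tested genes within 10 Mb of Lef1 by position on chromosome 3 (Mb, GRCm38), 1 point per gene, orange where the adjusted p was under 0.05. Lef1, Rpl34, Ccdc109b and Camk2d are the passing genes, at -1.27, -1.72, -1.53 and -0.78.

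Of the genes that the rule names, 2 that every cell uses were listed at 0 in both WT libraries: the translation elongation factor gene Eef1a1, with 7068 and 7188 FPKM in dKO, and the mitochondrial cytochrome oxidase gene mt-Co1, with 6204 and 6367 FPKM in dKO. Gm26377, a small RNA gene model inside Eef1a1 (chromosome 9, 78478528 to 78478635), was likewise listed at 0 in WT and at 118710 and 121994 FPKM in dKO. The summed FPKM of the libraries was 599231 and 619340 in WT and 726571 and 719527 in dKO. Eef1a1, mt-Co1 and Gm26377 enter these sums in dKO only, so the sums do not compare the remaining genes.

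The second experiment compared the 3 Treg subsets over features without gene names. The subset pair that differs in both gates, CD62L-TCF1- and CD62L+TCF1+ Treg, had 4148 of 11879 features past the threshold, 2259 higher and 1889 lower in CD62L-TCF1- Treg. The pair that differs in the TCF1 reporter had 2597 such features (1449 higher and 1148 lower in CD62L-TCF1- Treg). The pair of TCF1+ subsets, which differs in CD62L, had 970 (656 higher and 314 lower in CD62L-TCF1+ Treg). Changes of at least 1 on the log2 scale were made by 1098 higher and 535 lower, 471 higher and 305 lower, and 378 higher and 54 lower of these features, in the same order. Among the features that passed between the TCF1+ subsets, 67.6% were higher in CD62L-TCF1+ Treg, and this share was 80.3% to 91.0% with 1 library of that pair left out. For the TCF1 reporter pair 55.8% were higher in CD62L-TCF1- Treg, but 49.5% without CD62L-TCF1- replicate 1 or replicate 2. For the pair that differs in both gates 54.5% were higher, but 47.6% with quantile normalization (1973 higher and 2168 lower) and 49.4% with a mean of at least 5 FPKM (1503 and 1537), so neither direction prevailed in every setting.

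The standard deviation of the log2 difference between 2 libraries across features was 0.64, 0.65 and 0.77 within the CD62L+TCF1+, CD62L-TCF1+ and CD62L-TCF1- subsets. Between libraries of the TCF1+ subsets it was 0.72 to 0.78, between the CD62L- subsets 0.84 to 0.91, and between the subsets that differ in both gates 1.06 to 1.12. The comparisons share libraries and were not tested against each other. Leaving out 1 library of the compared TCF1+ subsets left 152 to 227 features. For the TCF1 reporter pair, 551 and 615 features passed without CD62L-TCF1+ replicate 1 or 2, and 1551 and 1543 without CD62L+TCF1+ replicate 1 or 2. For the pair that differs in both gates, 2121 and 2123 passed without CD62L+TCF1+ replicate 1 or 2.

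**Figure D4:**
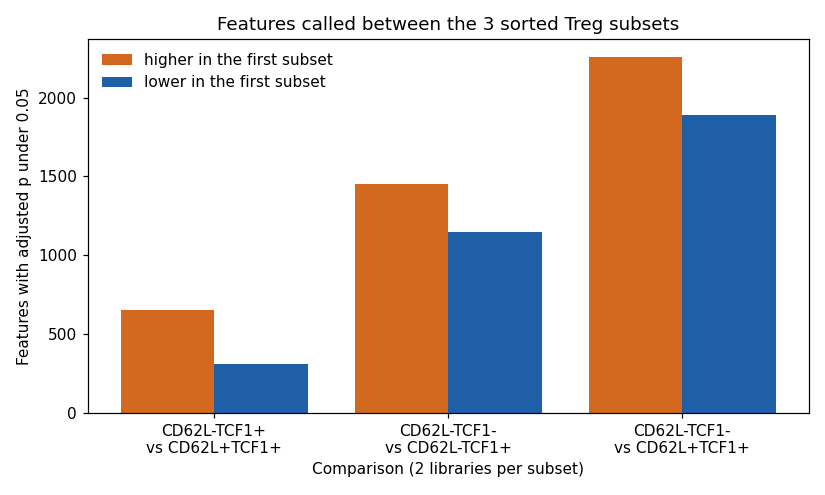
Number of features with an adjusted p under 0.05 in each comparison of the 3 sorted Treg subsets (2 libraries each), with bars from 0 for features higher (orange) and lower (blue) in the first subset named. The counts run from 314 to 2259.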

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

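The fits without genes listed at 0 and of protein-coding genes alone, and the list tests without Lef1 and Tcf7 as members, were chosen after seeing the data. The number of genes that passed between dKO and WT Treg (75) was the least stable result. It was 6 with no filter (all higher), 43 without the variance trend, 142 with robust variances and 230 at an adjusted p under 0.10. Leaving out 1 library gave 14 to 136 genes, where the lone library of a group is assumed to vary like the other group. Without genes listed at 0 in any library 117 genes passed, and 171 passed among protein-coding genes. The filter changes which genes enter the fit and the threshold changes by construction; for the other settings the cause was not tested. Pseudocounts of 0.1 and 0.5, median scaling, quantile normalization and a mean of at least 5 FPKM kept the count within 1.5 times. The count of 970 between the TCF1+ subsets was 618 with no filter, 1558 at an adjusted p under 0.10, 432 with an absolute log2 fold change of at least 1, and 152 to 1157 with 1 library left out. The count of 2597 for the TCF1 reporter pair was 1658 in a fit of its 4 libraries alone, 776 with an absolute log2 fold change of at least 1, and 551 to 2391 with 1 library left out. For the pair that differs in both gates the count of 4148 became 1633 and 2121 to 3963 in the last 2 settings. Fewer libraries leave fewer degrees of freedom, and the cause of these changes was not tested otherwise. With the replicate number as a block, 21 genes passed between dKO and WT (12 higher and 9 lower), and 895, 2595 and 4270 features between the subsets. The deviations of same-numbered libraries from their group means had a correlation of 0.014 for WT and dKO and of 0.107, 0.089 and -0.022 for the pairs of subsets, so only 1 of the 3 subset pairs was over 0.1 and the labels give no shared origin; the numbers were not taken to pair the libraries. Of the named genes' calls, no filter ended 19, leaving out WT replicate 2 or WT replicate 1 ended 16 and 15, the block 11 and no variance trend 8, while those of Nedd4, Eef1a1 and mt-Co1 held wherever these genes were tested. Lef1 had an adjusted p of 0.097 with no filter and 0.054 with the block. Tcf7 passed with robust variances (0.044), without genes listed at 0 (0.049) and among protein-coding genes (0.034). At the preset correlation, the calls of the follicular, Treg identity, interferon-stimulated and ribosomal protein lists held in every setting. The Treg identity median ranged from -0.61 to -0.24 and the follicular median from -0.68 to -0.32. None of the lists that passed reversed. Lists that did not pass were not counted as reversed, and the effector Treg median ranged from -0.37 to 0.12. Without Lef1 and Tcf7 the Wnt target list had a median of -0.27 over 9 members, against -0.31 over 11, and missed the threshold (adjusted p = 0.067). With an estimated correlation none of the 21 lists passed, nor did the added list (adjusted p = 0.13). The adjusted p of 0.65 that most lists share arises from the adjustment over the lists. Before it, the camera p ranged from 0.050 for interferon-stimulated genes to 0.90 for apoptosis genes. The subset signatures, the gene lists in the subsets, the relation of the knockout to the TCF1 gate and the joint fit of 10 libraries were not run, since they need gene names for the subset tables. Absolute depth is unknown, so the precision of low FPKM values could not be derived from counts.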

Other observations

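The genes in this paragraph lie outside the rule for named genes and were chosen after their values were seen. Cd4 did not pass the threshold. This gene, which encodes the coreceptor used for enrichment, had 384 and 411 FPKM in WT and 187 and 264 FPKM in dKO (log2 fold change -0.83, SE 0.17, limma adjusted p = 0.14). Thy1, a surface glycoprotein of T cells, fell from 437 ± 34.3 to 265 ± 8.87 FPKM (adjusted p = 0.0495). Mthfd2, a mitochondrial enzyme of folate metabolism, fell from 36.4 ± 0.74 to 13.6 ± 1.54 FPKM, and Adk, which encodes adenosine kinase, from 34.0 ± 0.94 to 16.0 ± 2.18 FPKM. Gas5, a noncoding RNA that hosts small nucleolar RNAs, fell from 482 ± 2.11 to 285 ± 10.6 FPKM. Faah, which degrades endocannabinoids, rose from 35.8 ± 0.28 to 59.5 ± 1.19 FPKM, and Crip1, a small LIM-domain protein, from 582 ± 4.96 to 1014 ± 96.0 FPKM.

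Of the tests below, only that on the medians of the marker lists was chosen before its result was seen; all the others were chosen after.

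Plac8, Cyp4f18, Cd86, Tlr7, Ifitm3 and Card9, which are known from B cells, myeloid cells or plasmacytoid dendritic cells, rose in dKO, and Cd86, Tlr7 and Card9 were chosen after their values were seen. From dKO replicate 1 to dKO replicate 2, 8 myeloid markers had a median log2 difference of 2.10 (0.83 to 4.15). The 6 genes had one of 0.14 (-0.46 to 0.29), a gap of 1.96 against SDs of 1.13 and 0.27. Of the markers, Spi1, Adgre1, Csf1r, Fcer1g and Fcgr3 reached 1 FPKM in dKO replicate 2 only. Part of the gap may therefore come from which markers were detected. Cd68, Tyrobp and Lyz2, which reached 1 FPKM in other libraries too, rose by 1.39, 2.29 and 4.15. The 6 genes did not follow Cd68, Tyrobp and Lyz2. This argues against myeloid cells that carry these 3 markers as the source of the rise in both dKO libraries. It does not decide for dKO replicate 2 alone or for myeloid cells without these markers. For B cells and plasmacytoid dendritic cells the tests did not decide either. Their lists had median log2 fold changes of 0.64 and 0.30, and the highest of the 3 cell types' lists, the myeloid one, had 0.866. The summed FPKM of 18 markers lay 9.60 above the WT mean in dKO replicate 1 and 82.0 in dKO replicate 2. This compares with 76.7 and 81.7 for the 6 genes and a difference of 9.51 between the WT libraries. The 18 markers include the 8 myeloid ones, of which Lyz2, Tyrobp and Csf1r had 31.9, 12.6 and 8.51 FPKM in dKO replicate 2. The sums were chosen after a comparison of log2 differences in dKO replicate 1 had not decided. Its medians were 1.56 for the 6 genes and 0.18 for the markers (SDs 1.33 and 0.55). The markers' share in such cells is not known here. Of the plasmacytoid list, Lair1, Ly6d and Ly6c2 lay 1.72, 0.83 and 0.67 above WT in dKO replicate 1, while Pld4, Tcf4 and Runx2 had 0.23, 0.09 and -0.13. Of the B cell list, H2-Aa, H2-Ab1 and H2-Eb1 had 0.46, 0.44 and 0.20, and Cd22 had -0.55. B cells, plasmacytoid dendritic cells and myeloid cells without Cd68, Tyrobp and Lyz2 may have passed the CD4 enrichment and the YFP sort. Such cells and a change in Treg themselves therefore cannot be told apart.

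Eef1a1 and mt-Co1 were listed at 0 in both WT libraries. Of 13 mitochondrially encoded protein genes, only 8 were tested, mt-Co1 among them, and the rest did not reach 1 FPKM in 2 libraries. The median log2 fold change of the 7 other tested ones was -0.0086, and mt-Cytb had 4751 and 5153 FPKM in WT and 4859 and 4939 FPKM in dKO. One of the 7, mt-Nd3, had only 0.53 and 1.45 FPKM in WT and 0.79 and 1.22 FPKM in dKO. Low listed values were therefore not confined to mt-Co1 or to WT. For mt-Co1, a failed estimate that was written as 0 could give such values, and a general loss of mitochondrial transcripts in WT could not. The mitochondrial genes do not bear on Eef1a1, which lies on chromosome 9, and the cause of its 0 was not tested. The genes listed at 0 nevertheless count among those that passed, as the report gives them.

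Within 10 Mb of Lef1 or Tcf7, 4 of 213 tested genes passed against 70 of 10474 elsewhere (odds ratio 2.84, 95% confidence interval 0.75 to 7.72, one-sided Fisher's exact p = 0.060). Of the 4, Gm25291 (0.51 Mb from Tcf7) was listed at 0 in both dKO libraries and at 7.65 and 10.4 FPKM in WT. The others, Rpl34, Ccdc109b and Camk2d, lie near Lef1 and were all lower in dKO. The test pools both windows, so it does not give the share of passing genes around Lef1 alone. The loxP-flanked alleles may carry an inherited segment whose genes differ, the deletion may act on neighbours, or the 4 genes may lie there by chance, and these cannot be told apart with 4 genes. Nedd4 and Myo6, with log2 fold changes of 4.08 and -3.37, both lie on chromosome 9 (72662346 to 72749852 and 80165031 to 80311729), outside both windows. The windows cover only the surroundings of Lef1 and Tcf7. Some passing genes, picked after their values were seen, lie close together elsewhere. On chromosome 8, Abhd8 (71456705 to 71463655) was lower and Cyp4f18 (71988482 to 72009626) higher. On chromosome 18, Gramd3 (56400337 to 56503792) and March3 (56761716 to 56925548) were both lower. On chromosome 1, BC094916 (173519717 to 173535957) and Pydc4 (173566283 to 173599274) were higher and Pydc3 (173673675 to 173698395) lower. Their log2 fold changes were 0.84, 0.90 and -1.71. Whether such neighbours are more frequent than by chance, or lie on another inherited segment, was not tested.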
